A study of Cupriavidus nantongensis with 6 samples.

How the data were processed

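Total RNA of 3 cultures grown with 4 mM CdCl2 and 3 cultures grown without it was sequenced, and the labels call the cultures biological replicates. Per the labels' protocols, cells grew in nutrient broth at 30 °C and 200 rpm, RNA was purified with a RiboPure kit and libraries were built with a NEBNext Ultra RNA kit. Whether ribosomal RNA was removed before sequencing, and whether counting used the strand of the reads, is not given in the sources used here, so reads of a gene and of a transcript on its opposite strand cannot be told apart.

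The authors deposited a table of raw read counts per gene, whole numbers with no normalization, for the 6 libraries. The submitters' processing notes name cutadapt 1.9.1, Bowtie2 2.2.6 and HTSeq 0.6.1p1 without saying what each did. The genome build behind the scaffold positions is not given in the sources used here, and no reference genome was used. The table listed 5540 genes on 67 scaffolds with start and end positions, and the coding length of all 5540 is a multiple of 3. A COG family was given for 4605 genes, with a family name for 3565, while 935 genes had none. KEGG entries were given for 1815 genes and Gene Ontology biological processes for 1164. Gene names in the text are COG family names, so several genes share a name and are told apart by identifier.

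Total counts ran from 5364895 to 6471898 per library. A count of 3, taken as the floor for a gene with no reads, equals between 0.464 and 0.559 CPM, which covers counting error only. The common biological coefficient of variation was 9.87%. Differences between replicates exceeded sampling noise in every pair of libraries within a group, with a chi-square per degree of freedom from 5.95 to 9.36, which does not tell separate cultures from separate libraries of the same culture.

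From the deposited counts, genes with low counts were removed with edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total count 15), which left 4752. Scaling factors were computed by TMM. The treated and control groups were compared with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries. Standard errors of log2 fold changes were taken as the absolute value divided by the square root of F.

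Gene lists were fixed before the data were examined, 30 in all, from knowledge of metal resistance, stress and growth. Their names were matched to COG family names and descriptions. Lists for heavy-metal efflux of the RND type and for stable RNAs matched no gene, and 28 were tested by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, 2-sided, lists of at least 3 tested genes), adjusted over the 28. With the preset correlation 12 lists were called. With an estimated correlation none of the calls held, and 6 lists had an unadjusted p under 0.05. These losses are not by themselves a sign of correlated genes, since some lists had an estimate no higher than the preset. The test fry, which asks whether genes of a list move on balance in 1 direction without comparing them with other genes, called 27. Members were also counted with p-values adjusted over the list alone. After the values were seen, 4 lists of pump and regulator families were added by COG family, and 10 lists were repeated without families that do not do what the list's name says.

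The genes named in the text follow a rule fixed before the data were examined. It took the 8 annotated genes with the highest and the 8 with the lowest log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 CPM and groups that do not overlap. It took up to 6 members changed at least 2-fold from each list of metal export and sensing, up to 3 members with the smallest p from each other list called by camera, and 1 member from each list not called. It named 68 genes. Other genes in the text were chosen after their values were seen. They are NirB, NirD and the NarK 12_52, SodA, Bcp, Tpx, the AHP1 gene 17_35, the osmC genes 6_111, 9_135 and 10_109, PrmA and CcoN. The CyoB genes 4_479, 1_473 and 11_15, the CzcD genes 29_5 and 16_4 and the Nuo genes that rose are also among them. So are the genes 6_195 to 6_197, the putative silver efflux pumps with the membrane-fusion and TolC genes near them, and all genes of the closing section not named before.

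Alternatives were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, no filter, a filter at a mean of 10 CPM, the replicate number as a block, and each library left out in turn. Removal of the 100 most abundant genes and thinning of every library to the lowest total were added after the values were seen. The model was tested on simulated data, counts with known changes. For CdCl2 against control (4349 genes), edgeR recovered 43.5% of genes with a log2 change of 0.5, 81.7% at 1 and 100% at 2, and called 9 of 4166 unchanged genes. Most simulated genes were thus unchanged, while 3798 of 4752 real genes were called, so these rates need not carry over. In simulated lists, camera called 0 of 20 flat lists and 1 of 1 raised list with each kind of correlation, and fry gave the same. Genes were simulated independently and most did not change. The simulated lists therefore cannot tell which kind of correlation suits the real data, nor how fry behaves where most genes change. Scripts ran in R 4.3.3, and figures were drawn with matplotlib 3.10.9.

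A planned comparison by replicon was not run, since the scaffolds were not assigned to replicons. A planned removal of ribosomal and transfer RNA genes removed nothing, since the annotation names none. Sequences of similar genes were not compared.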

Results

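Transcript levels were measured by RNA sequencing in Cupriavidus nantongensis strain E324, a betaproteobacterium, after growth with or without cadmium chloride. Log-phase cells entered nutrient broth at a starting optical density of 0.1 and were grown at 30 °C for 2 h, a time the labels equate with 2 doublings. The treated cultures received 4 mM CdCl2, the dose that the labels give as inhibiting growth by 90%. There were 3 treated and 3 untreated cultures. The labels call the cultures of each group biological replicates. The table of counts held 5540 genes on 67 scaffolds. Total counts per library were 5429362, 5648633 and 5364895 with CdCl2 and 6236208, 6471898 and 5960749 in the controls. Genes are given by the family name of their best match among clusters of orthologous groups (COG) and by their identifier, in which the scaffold number precedes the gene number. A COG family name describes a family of proteins and does not fix the substrate of a single member.

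The comparison addressed which genes change in transcript level when the cells meet cadmium. With the preset correlation, camera called 5 gene lists higher with CdCl2: P-type metal ATPases, copper resistance, oxidative stress defence, sulphate assimilation, and thiol and glutathione systems. None of these calls held with an estimated correlation (adjusted p from 0.146 to 0.324), and 1 of the ATPases, 6 genes of oxidative stress defence, 3 of sulphate assimilation and 12 of thiol and glutathione systems fell. In the same way 7 lists were called lower: ribosomal proteins, translation factors, ATP synthase, NADH dehydrogenase, nitrate respiration, flagella and chemotaxis, and exopolysaccharide. With an estimated correlation these calls were lost too (adjusted p from 0.146 to 0.418), and 5 translation factors or tRNA synthetases, 3 genes of NADH dehydrogenase, 3 of nitrate respiration, 25 of flagella and chemotaxis and 2 of exopolysaccharide rose. Of 4752 genes tested with edgeR's quasi-likelihood F test, 3798 (79.9%) had a Benjamini-Hochberg adjusted p under 0.05, with 1913 higher and 1885 lower. At least a 2-fold change was found for 2655 genes, of which 1439 were higher and 1216 lower. Replicates of a group had Pearson correlations of log2 CPM between 0.989 and 0.990 across genes, against 0.681 to 0.709 between groups. Counts were scaled to a common total, so each change is relative to the other transcripts of the cell and total RNA per cell was not measured.

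Most cation-transporting P-type ATPases, which pump metal ions out of the cytoplasm, were higher with CdCl2. Of 9 measured members of this list, all placed in the ZntA family, 8 rose and 1 fell, and the counts were the same when adjusted over the list alone. The member 18_2 (scaffold 18, positions 922 to 3951) rose from 89.3 ± 1.61 to 7564 ± 445 CPM (mean ± SD, n = 3 per group), an 84.7-fold change. The member 35_6 (scaffold 35, positions 2923 to 5955) rose 50.3-fold, from 163 ± 8.38 to 8181 ± 399.7 CPM. Rises of 65.9-fold, 40.3-fold and 20.2-fold were found for 18_61, 7_242 and 13_5. The member that fell, 5_232, was 18.01-fold lower and lies beside the genes of the cbb3-type oxidase. The list was called higher by camera with the preset correlation (adjusted p = 0.00306, median log2 fold change 4.33), and had an adjusted p = 0.324 with an estimated correlation.

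Cation diffusion facilitators, a second type of metal exporter, changed in part. Of 6 members of the list of these and other single-protein exporters, 2 rose, none fell and 4 did not pass the test, also when adjusted over the list alone. Both that rose were CzcD-family genes that directly follow ZntA-family genes in the numbering. Gene 18_3 went from 3.37 ± 0.786 to 399 ± 2.84 CPM (118-fold) and 35_7 from 4.75 ± 0.993 to 449 ± 25.8 CPM (94.4-fold). The CzcD-family genes 29_5 and 16_4 had log2 fold changes of -0.18 and -0.16. The pairs 18_2 with 35_6 and 18_3 with 35_7 have nearly the same coding length and family, their sequences were not compared here, and counts of near-identical copies are uncertain. The list as a whole was not called (camera, adjusted p = 0.480).

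Of 5 ArsR-family regulators in the list of metal sensors, 3 rose and none fell, also when adjusted over the list alone. Gene 19_60 rose 59.2-fold to 879 ± 106 CPM and 10_57 rose 31.9-fold to 93.3 ± 11.6 CPM. The call of 4_117 (2.10-fold, adjusted p = 0.0289) was lost with upper-quartile scaling (adjusted p = 0.0510), with DESeq2 (0.0733), and when CdCl2 replicate 1 (0.0573), CdCl2 replicate 2 (0.0807), Control replicate 1 (0.0577) or Control replicate 3 (0.145) was left out. The list was not called (camera, adjusted p = 0.292). In the list of mercury and arsenic resistance, 2 of 5 members rose and 3 fell, also when adjusted over the list alone. It was matched by COG family name and description, so resistance genes placed in broader families would be missed. Its counts therefore do not show whether mercury resistance as a whole responded. The arsenite pump ACR3 (19_58), a neighbour of 19_60, rose 58.5-fold. This list was not called (camera, adjusted p = 0.908), and its median log2 fold change of -0.54 and the camera direction had the opposite sign to its mean of 0.64.

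**Figure D1:**
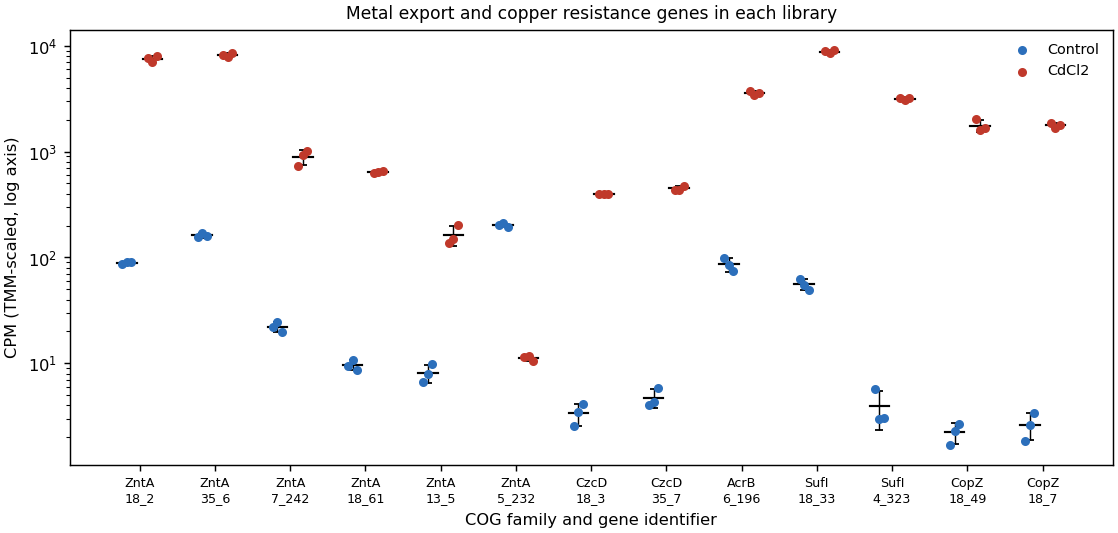
Normalised CPM (log axis) of 13 genes of metal export, copper resistance and RND efflux in each of 6 libraries. Points show the 3 libraries of a group, a black line the mean and bars the SD. The RND gene, 6_196, is of the AcrB family of cation/multidrug efflux pumps, which does not fix its substrate. In 12 of the genes the CdCl2 libraries lie above the controls, and in 5_232 they lie below, with means of 11.3 and 203 CPM.

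Genes of the copper resistance list, from families that bind, carry or oxidise copper or are tied to resistance to it, rose together. All 14 measured members rose, also when adjusted over the list alone, with a median log2 fold change of 7.38 (167-fold) and a range from 3.30 to 9.65. The PcoB-family gene 4_324 rose from 2.27 ± 0.468 to 1844 ± 147 CPM (802-fold), and its neighbours 4_323 (SufI, a multicopper oxidase) and 4_325 (CopC) rose 802-fold and 746-fold. The CopZ-family genes 18_49 and 18_7 rose 787-fold and 670-fold. Their family is described as copper chaperones, which does not fix the metal that these genes bind. Control counts of these 5 genes were low, with sums over the 3 libraries from 39 to 69, so their fold changes are known less well than their levels with CdCl2. The multicopper oxidase 18_33 reached 8810 ± 310 CPM, against 55.7 ± 6.60 in the controls. Camera called it higher (adjusted p = 3.87e-07), with an adjusted p = 0.146 with an estimated correlation.

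**Figure D2:**
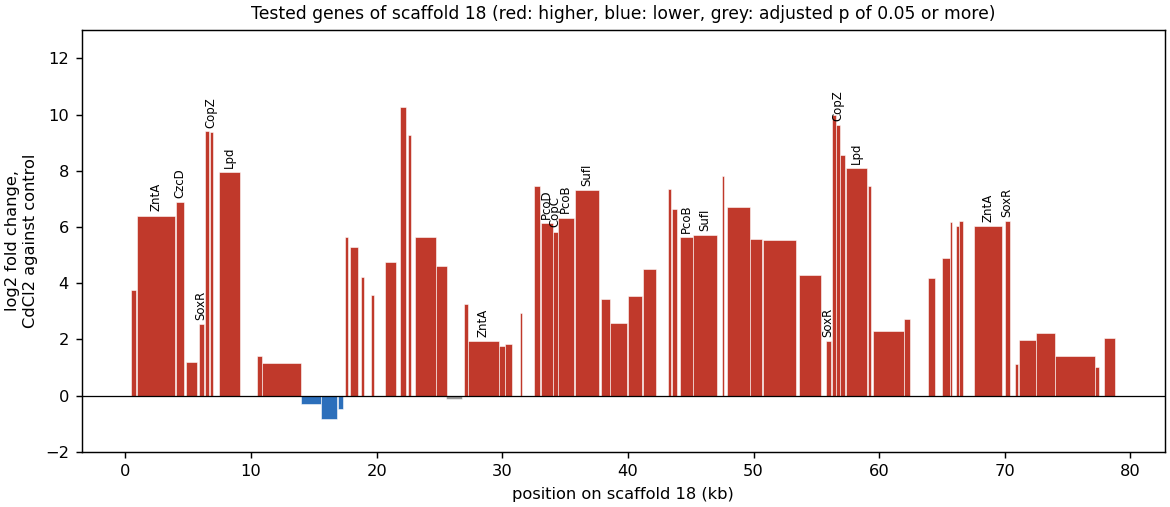
Log2 fold change with CdCl2 against control for the 67 tested genes of scaffold 18, drawn as bars over the position of each gene in kb, with red for higher, blue for lower and grey for an adjusted p of 0.05 or more. Higher levels were found for 63 genes and lower levels for 3, and the named ZntA, CzcD, CopZ, PcoB and SufI families all lie among the higher ones.

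Genes of oxidative stress defence moved both ways, more of them up than down. In the list of oxidative stress defence, 17 of 28 members rose and 6 fell, also when adjusted over the list alone. The peroxiredoxin AHP1 (6_178) had the greatest fold change of the annotated genes named by the fixed rule, from 13.8 ± 1.25 to 13732.5 ± 819.9 CPM (994-fold; log2 fold change 9.96, SE 0.13, adjusted p = 3.04e-18 by edgeR). The organic hydroperoxide reductase osmC (15_2) rose 289.6-fold and the catalase KatE (2_234) rose 48.9-fold, to 14215 ± 1415 and 14198 ± 371 CPM. Further members of such families moved both ways: the osmC gene 10_109 rose 2.93-fold, the peroxiredoxins Bcp (5_183) and Tpx (2_298) were 2.03-fold and 1.42-fold lower, another AHP1 gene (17_35, adjusted p = 0.445) and the osmC genes 6_111 (0.537) and 9_135 (0.521) did not pass, and the superoxide dismutase SodA (1_842) fell by 0.32 on the log2 scale. The list was called higher (camera, adjusted p = 0.00467, median log2 fold change 1.83), with an adjusted p = 0.146 with an estimated correlation. It took in 11 genes of the SoxR family, a COG family that holds MerR-type regulators in general, many of which sense metals. Without them, 10 of 17 members rose and 3 fell (adjusted p = 0.0182; adjusted p = 0.381 with an estimated correlation), a set chosen after the values were seen.

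Most genes of sulphate assimilation and thiol chemistry were higher. In the list of sulphate uptake and cysteine synthesis, 16 of 23 members rose and 3 fell, also when adjusted over the list alone. The sulphite reductase CysI (2_108) rose 5.41-fold to 2215 ± 222 CPM, the CysH-family enzyme 2_105, of the step that yields sulphite, 4.98-fold and the serine acetyltransferase CysE (1_324) 5.41-fold. Taken as a whole it was called higher (camera, adjusted p = 0.00597, median log2 fold change 1.75), with an adjusted p = 0.324 with an estimated correlation. Of 55 genes for thiol and glutathione systems, 39 rose and 12 fell, also when adjusted over the list alone. Glutathione S-transferases moved both ways, with 1_453 higher 19.96-fold, 3_225 higher 7.83-fold and 14_90 lower 8.66-fold. The list was called higher (camera, adjusted p = 0.00230, median log2 fold change 1.11), with an adjusted p = 0.146 with an estimated correlation. It also held ArsC-family, GloA-family and GloB-family genes, which act on arsenate or on other small molecules, and without these, a set chosen after the values were seen, 25 of 36 members rose and 9 fell (adjusted p = 0.0129; adjusted p = 0.246 with an estimated correlation).

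Most genes of the translation machinery were lower with CdCl2. Of 56 members of the ribosomal protein list, 55 fell and none rose, also when adjusted over the list alone. The exception was PrmA (2_296), a methylase that acts on a ribosomal protein, with a log2 fold change of -0.18. The median log2 fold change was -2.04, a 4.11-fold lower level, and RpmE (8_398) went from 4280 ± 183 to 628 ± 41.98 CPM. RpsB (5_65) was 5.26-fold and RplQ (14_153) 5.27-fold lower. Camera called this list lower (adjusted p = 1.97e-13), with an adjusted p = 0.388 with an estimated correlation. Among 49 translation factors and tRNA synthetases, 42 fell and 5 rose, also when adjusted over the list alone, and the elongation factor Tsf (5_64) was 6.09-fold lower. The FusA-family genes 9_152 and 7_68, of the family of elongation factor G, rose 18.8-fold and 12.2-fold. This list was called lower (camera, adjusted p = 3.87e-07), with an adjusted p = 0.146 with an estimated correlation.

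**Figure D3:**
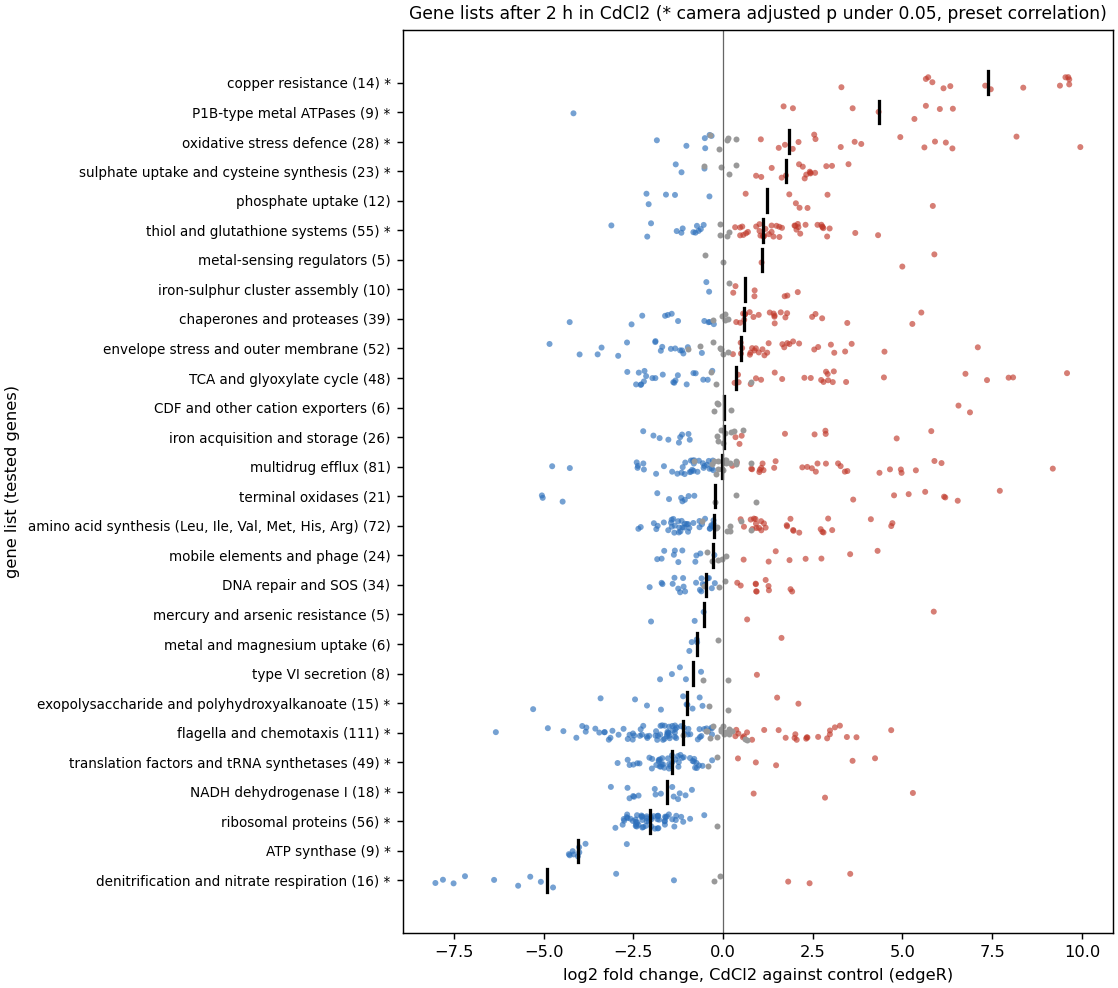
Log2 fold change of each tested gene (horizontal axis, CdCl2 against control) in the 28 gene lists, with list sizes in brackets, red points for genes that rose, blue for genes that fell, grey for genes that did not pass the test and black lines for list medians. Stars mark the 12 lists called by camera with the preset correlation, of which 5 were higher and 7 lower.

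Most genes for nitrate respiration, which lets cells use nitrate as an electron acceptor when oxygen is scarce, fell. In the list of denitrification and nitrate respiration, 11 of 16 members fell and 3 rose, also when adjusted over the list alone. The nitrate reductase gene NarG (4_267; scaffold 4, positions 284600 to 288346) went from 13983 ± 692 to 53.9 ± 2.39 CPM (259-fold lower). Its neighbours NarY (4_266), NarK (4_268) and NarK (4_269) were 83.5-fold, 146-fold and 183-fold lower. The nitric oxide reductase NorB (4_219) was 224-fold lower, and the adjacent gene 4_218, placed in a family of regulators of nitric oxide signalling, 202-fold lower. The members that rose were a NarK-family transporter on another scaffold (12_52), NirB (22_6) and a NirD-family gene (22_5), which belong to families of nitrate transport and assimilatory nitrite reduction. The list was called lower (camera, adjusted p = 0.00306), with an adjusted p = 0.146 with an estimated correlation. Its median log2 fold change was -4.91, and -1.39 without a filter on low counts, where more members of low count enter.

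Other parts of the respiratory chain changed in both directions. All 9 genes of ATP synthase fell, also when adjusted over the list alone, with a median log2 fold change of -4.05 (16.5-fold lower), including AtpF (10_125), which went from 1165 ± 49.5 to 59.1 ± 19.9 CPM. AtpH (10_124) was 16.1-fold lower and AtpI (10_128) 6.42-fold lower. That list was called lower (camera, adjusted p = 0.000527), with an adjusted p = 0.418 with an estimated correlation. Of 18 members of the NADH dehydrogenase list, 15 fell and 3 rose, also when adjusted over the list alone, with NuoJ (1_486), NuoL (1_484) and NuoM (1_483) lower 6.10-fold, 5.68-fold and 6.34-fold. Those that rose were 1_812, 1_813 and 7_201, NuoF-family and NuoE-family genes outside the row of genes from 1_482 to 1_495. This list was called lower (camera, adjusted p = 0.00230), with an adjusted p = 0.418 with an estimated correlation. Among 21 terminal oxidase genes, 8 rose and 10 fell, and 10 rose and 10 fell when adjusted over the list alone. The CyoB-family gene 4_42 rose 73.1-fold to 247 ± 8.89 CPM, and 4_479 rose 27.2-fold to 112 ± 5.32 CPM. The CyoB-family genes 1_473 and 11_15 were 1.95-fold and 1.74-fold lower, and stayed at higher levels with CdCl2, 660 ± 62.5 and 455 ± 7.91 CPM. FixS (5_231), a small protein of cbb3 oxidase assembly, fell to a level near the floor of counting, with sums over the 3 libraries of 8 counts with CdCl2 and 560 in the controls, so no fold change is given, and the oxidase subunit CcoN (5_230) beside it went from 2325 ± 206 to 70.1 ± 13.5 CPM. The oxidase list was not called (camera, adjusted p = 0.918), and its median log2 fold change of -0.22 and the camera direction had the opposite sign to its mean of 1.13.

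**Figure D4:**
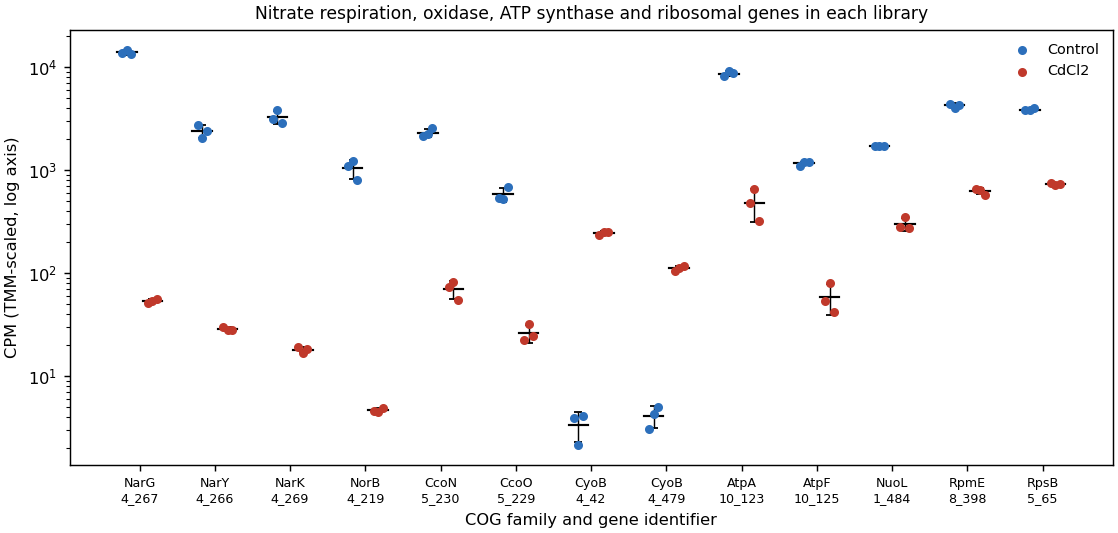
Normalised CPM (log axis) of 13 genes of nitrate respiration, oxidases, ATP synthase, NADH dehydrogenase and ribosomal proteins in each of 6 libraries, with points for the 3 libraries of a group, a black line for the mean and bars for the SD. The CyoB-family genes 4_42 and 4_479 lie higher with CdCl2, and the other 11 genes lie lower. The CyoB-family genes 1_473 and 11_15, which fell, are not drawn.

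Most genes of the motility list were lower. In the list of flagella and chemotaxis, 70 of 111 members fell and 25 rose, also when adjusted over the list alone. The members with the smallest p were AtoC (4_190), OmpR (4_322) and CitB (12_114), response regulators of signalling systems in general, which rose 13.2-fold, 25.7-fold and 7.87-fold. The gene 4_322 lies beside the copper-resistance gene 4_323. Another CitB-family response regulator, 4_208, was 80.7-fold lower, a value that rests on a sum of 15 counts with CdCl2. Without such response regulators, a set chosen after the values were seen, 49 of 55 members fell and 2 rose, with a median log2 fold change of -1.74 (adjusted p = 7.19e-08; adjusted p = 0.150 with an estimated correlation). The full list was called lower (camera, adjusted p = 0.00230, median log2 fold change -1.13), with an adjusted p = 0.146 with an estimated correlation.

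Of 15 genes for exopolysaccharide and polyhydroxyalkanoate, 11 fell and 2 rose, also when adjusted over the list alone. GumC (2_18) was 10.7-fold lower and the export proteins Wza 5_13 and 6_293 were 39.3-fold and 5.48-fold lower. The level of 5_13 with CdCl2 varied between libraries, at 10.4 ± 8.91 CPM. The list was called lower (camera, adjusted p = 0.0427, median log2 fold change -0.99), with an adjusted p = 0.262 with an estimated correlation. The call was lost without Control replicate 3 (adjusted p = 0.0523).

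General stress lists were mixed and not called by camera. Of 39 chaperones and proteases, 23 rose and 11 fell (adjusted p = 0.138), and the small heat shock protein IbpA (1_195) rose 46.0-fold. Of 34 genes for DNA repair, 11 rose and 20 fell (adjusted p = 0.292), and a UvrD-family helicase (14_88) rose 3.80-fold. Of 52 genes for the outer membrane and envelope stress, 28 rose and 17 fell (adjusted p = 0.677), and OmpW (9_94) was 28.6-fold lower. For iron acquisition and storage, 9 of 26 members rose and 9 fell, or 8 and 9 when adjusted over the list alone (adjusted p = 0.975), and bacterioferritin Bfr (16_6) rose 28.6-fold. Iron-sulphur cluster assembly had 7 of 10 members higher and 2 lower (adjusted p = 0.235), with sufA (1_964) higher 3.46-fold. Uptake of metals and magnesium had 1 of 6 members higher, the molybdate-binding ModA (3_131, 3.09-fold), and 4 lower (adjusted p = 0.381). For phosphate uptake, 7 of 12 members rose and 5 fell (adjusted p = 0.476), and PhoD (26_15) rose 57.5-fold. Apart from iron acquisition, the counts in these lists were the same when adjusted over the list alone.

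Central metabolism and the remaining lists also moved both ways, with no call by camera. Of 48 genes of the TCA and glyoxylate cycle, 24 rose and 21 fell (adjusted p = 0.918). Its member with the smallest p, Lpd (6_179), lies beside the peroxiredoxin 6_178 and rose 769-fold, from a sum of 48 control counts. It belongs to a broad family of flavin disulphide reductases that also holds enzymes outside the cycle. Of 72 genes for the synthesis of 6 amino acids, 27 rose and 37 fell (adjusted p = 0.480, median log2 fold change -0.27, mean 0.16, camera direction lower), and IlvD (9_19) rose 26.3-fold. Type VI secretion had 5 of 8 members lower and 1 higher (adjusted p = 0.164), with VgrG (6_226) lower 3.38-fold. For mobile elements, 8 of 24 members rose and 11 fell (adjusted p = 0.677, median -0.27, mean 0.19, camera direction lower), and a transposase on scaffold 18 (18_46) rose 19.8-fold. For multidrug efflux, 29 of 81 members rose and 34 fell (adjusted p = 0.975, median -0.02, mean 0.51, camera direction higher), and its member with the smallest p, AcrR (6_272), is of a regulator family and rose 584-fold. The counts in these lists were the same when adjusted over the list alone.

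The fixed list of heavy-metal efflux pumps of the RND type matched no gene, since the family names in the table do not carry those names. RND pumps were therefore listed by COG family after the values were seen. Of 16 pump proteins, 6 rose and 4 fell (camera over the 4 added lists, adjusted p = 0.298). Some are described as putative silver efflux pumps, the others as cation/multidrug pumps of the AcrB family. Of the putative silver pumps, 7_170 rose 14.0-fold, 7_135 4.40-fold, 18_66 2.63-fold and 18_10 2.23-fold. Gene 29_6 was 1.22-fold lower, and 3_150, 3_212 and 4_133 did not pass. The AcrB-family gene 6_196, described as a cation/multidrug efflux pump, rose 41.4-fold to 3582 ± 162 CPM. Its neighbours 6_195 (a membrane-fusion protein) and 6_197 (a TolC-type channel) rose 31.0-fold and 53.0-fold. Of 17 membrane-fusion proteins, 7 rose and 4 fell, of 20 TolC-type channels, 11 rose and 5 fell (both adjusted p = 0.298), and of 11 MerR-type regulators, 7 rose and 3 fell (adjusted p = 0.208). Counts in these 4 lists were the same when adjusted over the list alone.

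Beyond these lists, a pair of neighbouring genes on scaffold 4 was among the 8 annotated genes with the highest fold change. The acyl-CoA transferase CaiB (4_538) went from 1.18 ± 0.469 to 1196 ± 56.9 CPM (983-fold), and the biotin carboxylase AccC (4_537) from 2.19 ± 1.29 to 1801 ± 179 CPM (804-fold). Control counts of both genes were low, with sums over the 3 libraries of 21 and 39, so the fold changes are known less well than the levels with CdCl2.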

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

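Leaving out family mismatches, the 100 most abundant genes or surplus depth was chosen after the results were seen, and the other alternatives before. The count of changed genes ran from 2946 (mean of at least 10 CPM, with fewer genes tested) to 3950 (no filter on low counts), against 3798, and from 3697 to 3735 with a library left out. DESeq2 gave 3714 and limma-voom 3789, and in none of the 17 alternatives was a gene called in the opposite direction. Upper-quartile scaling moved the median log2 fold change of all genes from 0.01 to -0.12 and library size alone to 0.19, with 1787 higher and 2025 lower, and 2099 higher and 1677 lower. With an estimated correlation 0 lists were called by camera, and 6 had an unadjusted p under 0.05. The adjusted p was then 0.146 for copper resistance, thiol and glutathione systems, oxidative stress defence, translation factors and tRNA synthetases, denitrification, and flagella and chemotaxis, 0.262 for exopolysaccharide, 0.324 for P-type ATPases and sulphate uptake, 0.388 for ribosomal proteins, and 0.418 for ATP synthase and NADH dehydrogenase. The estimated correlation was no higher than the preset 0.01 for copper resistance (0.00989), exopolysaccharide (-0.0670) and denitrification (-0.0453). The same held for thiol and glutathione systems (0.00331) and oxidative stress defence (-0.0222). For these lists that argues against a higher correlation between genes as the cause of the lost calls. For the other called lists the estimate was higher, up to 0.814 for ATP synthase. At nearly the same correlation, the camera adjusted p for copper resistance went from 3.87e-07 to 0.146. The settings of camera thus differ in more than the correlation, and what else differs was not tested. The test fry, which compares a list with no change instead of with other genes, called 27 lists. Among lists not called by camera its adjusted p was 2.13e-05 for cation exporters and phosphate uptake, 4.07e-05 for metal-sensing regulators and multidrug efflux, 6.99e-05 for chaperones, 7.98e-05 for iron acquisition, 8.27e-05 for the TCA cycle, 8.81e-05 for type VI secretion, 0.000171 for iron-sulphur assembly, 0.000196 for DNA repair, 0.000381 for the envelope, 0.00258 for metal uptake and 0.00490 for amino acid synthesis. With fry the direction turned to higher for mercury and arsenic (0.000196), terminal oxidases (0.00369) and mobile elements (0.105). Turns among lists that stayed without a call, whose cause was not tested, were multidrug efflux to lower with upper-quartile factors (adjusted p = 0.995) and no filter (0.945), iron acquisition to lower with no filter (0.858), the envelope (0.968) and TCA cycle (0.799) to lower and mobile elements to higher (0.968) at a mean of at least 10 CPM, and the TCA cycle to lower without mismatched families (0.453). With a library left out, adjusted p ran from 0.918 to 0.982 for iron acquisition, which turned to lower without CdCl2 replicate 1 or 3 or Control replicate 1 or 2. It ran from 0.941 to 0.995 for multidrug efflux, which turned to lower without Control replicate 1, 2 or 3. For exopolysaccharide it ran from 0.0291 to 0.0523, above the threshold without Control replicate 3. Of the named genes, the ArsR gene 4_117 alone lost its call, in 6 alternatives. Small changes can be missed: the simulation recovered 43.5% at a log2 change of 0.5. In it 4166 of 4349 genes were unchanged, unlike the real data, so this rate need not hold here.

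With the replicate number as a block (replicate block), 3760 genes were called, 1895 higher and 1865 lower, and multidrug efflux turned to lower (adjusted p = 0.985), which changed no call of a list. Deviations from group means of same-numbered libraries correlated at 0.0025, -0.058 and 0.029 across genes, which gives no sign that the numbers pair the libraries.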

Other observations

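The tests of scaffold 4, of the count ratio of gene pairs, of the 100 most abundant genes, of thinning, of gene runs, of scaffolds, of read shares and of COG and Gene Ontology groups were chosen after the results were seen, and that of the cytochrome bd genes after the fall of the nitrate genes but before its own value. Part of the genes with large changes lay side by side. Of all tested genes, 465 were at least 8-fold higher, within runs or outside them. Runs of at least 4 neighbouring genes changed at least 8-fold in the same direction numbered 41, with 33 higher, 8 lower and 230 genes in all. Shuffling gene order 1000 times gave at most 3 runs (permutation p = 0.001, the smallest these permutations can give). The longest run, 5_1 to 5_15 (scaffold 5, positions 136 to 19791), holds families of polysaccharide synthesis and export and was lower by a median of 19.9-fold, with a sizeable spread among treated libraries, such as 62.2 ± 44.6 CPM for BacA (5_15) against 2371 ± 186 in the controls. Runs that were higher held HutU, HutH and HutI of histidine breakdown (2_138 to 2_142, median 42.02-fold), GlgP, GlgB and other glycogen enzymes (7_292 to 7_297, 47.2-fold), the UgpB, UgpA and UgpE families of sugar transport (8_342 to 8_347, 32.8-fold), SpoVR and PrkA (3_52 to 3_55, 77.3-fold) and the DNA-end-binding Ku homolog with its neighbours (4_180 to 4_186), where control levels of several genes lay below the floor and no fold change is given. Control counts were low in the glycogen run too, so its fold change is known less well than its direction. On scaffold 18, 45 of 67 tested genes (67.2%) were at least 8-fold higher, against 9.79% of all tested genes (Fisher's exact test over 33 scaffolds, adjusted p = 6.15e-29). Neighbours in an operon are not independent, so that p and the permutation p for runs both overstate the evidence.

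Groups of genes tested by annotation moved both ways. Of the 102 Gene Ontology processes, camera called 16 lower and 2 higher. Those higher were copper ion transport (6 of 7 genes higher, adjusted p = 0.0180; adjusted p = 0.329 with an estimated correlation) and the cellular response to DNA damage (8 of 8 higher, adjusted p = 0.00317; adjusted p = 0.329 with an estimated correlation), whose members belong to families such as PstS, NarK and SpoVR. The response to cadmium ion was not called (1 of 10 genes higher, 3 lower, adjusted p = 0.729). Histidine breakdown to glutamate and formate was not called by camera either (6 of 7 genes higher, 1 lower, adjusted p = 0.0542, and 0.329 with an estimated correlation). All 19 tested genes annotated to peptidoglycan synthesis fell (median log2 fold change -1.26, adjusted p = 0.000141; adjusted p = 0.329 with an estimated correlation), among them MurD (17_27) at 58.3 ± 12.1 against 192 ± 7.98 CPM. All 10 genes of IMP synthesis fell (adjusted p = 0.00317; adjusted p = 0.329 with an estimated correlation). No process was called with an estimated correlation, and 8 had an unadjusted p under 0.05. Of the 23 COG categories, 7 were called lower and 2 higher. Motility (74 of 86 genes lower, 3 higher) and trafficking (85 of 120 lower, 22 higher) were called lower with an estimated correlation too (adjusted p = 0.0334 for both). Translation (142 of 185 lower, 30 higher, adjusted p = 2.23e-09), cell division, DNA replication and repair, nucleotide metabolism and vesicular transport were called lower with the preset correlation only. Lipid metabolism (217 genes, median log2 fold change 0.72) and secondary metabolites (175 genes, 0.65) were called higher (adjusted p = 0.00778 for both), but not with an estimated correlation (adjusted p = 0.118 and 0.0502). Genes without a COG family took 15.8 ± 0.357% of reads with CdCl2 and 6.05 ± 0.112% in the controls (n = 3, exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allows). The unannotated gene 6_270 (scaffold 6, positions 302568 to 303074) reached 21194 ± 580.1 CPM from 42.2 ± 2.88, and 7_235 reached 17851 ± 824 CPM from 23.6 ± 4.99. Both lengths, 507 and 276 bases, are those of short proteins.

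That 79.9% of tested genes were called could come from scaling or depth. Without the 100 most abundant genes the share called was 79.6%, and with every library thinned to the lowest total 3736 genes were called, which argues against abundant genes and against depth as the whole cause. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes, with 3798 called by edgeR, and the highest of the others gave 0, where 5 to 17 genes had an unadjusted p under 0.05. Each of the other splits mixed treated and control libraries within a group, which widens the spread there. Their low counts are therefore no measure of what chance would give. A response to cadmium and any slower growth at a dose given as inhibiting by 90% stay open, since the design does not part them.

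Of 16 genes in the list of nitrate respiration, which serves cells short of oxygen, 11 were lower with CdCl2 and 3 higher (adjusted p = 0.146 with an estimated correlation), and the genes CcoN, CcoO, CcoQ and FixS of the cbb3-type oxidase, which were not tested as a list, were lower. A lower yield of scaffold 4 as a whole would lower its other genes too, but 462 other tested genes there had a median log2 fold change of 0.56, which argues against it for the 8 nitrate genes on that scaffold, while the cbb3 genes lie on scaffold 5 and were not covered by this test. A hypothesis is that treated cultures, if they grew less, kept more oxygen than the controls, which may lower such genes without a direct effect of the metal. The cytochrome bd genes, which also serve at low oxygen, had a median log2 fold change of 0.36 (SD 0.57 over 3 genes). None was called by edgeR over all genes. Adjusted over the list of terminal oxidases alone, 6_280 and 4_530 were called higher (adjusted p = 0.0459 for both). Gene 4_530 had sums of 38 counts with CdCl2 and 20 in the controls. Gene 6_281, with the most counts of the 3, was lower and not called (adjusted p = 0.0564). These genes cannot decide on that hypothesis, since they moved both ways and the spread reaches below 0 (a reading added after the value was seen). Oxygen supply and a direct effect of cadmium cannot be told apart, because culture density was not analysed here and the growth inhibition that the labels give for the dose goes with the treatment.

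The ZntA-family and CzcD-family neighbours of scaffolds 18 and 35 rose together, and reads of near-identical copies could be divided between them. If a single active copy had its reads divided at random, the count ratio of 18_2 to 35_6 would be the same in both groups. It was 0.924 ± 0.00996 with CdCl2 and 0.550 ± 0.0222 in the controls (n = 3, exact permutation p = 0.1, 2-sided, the smallest possible), a difference of 0.375 with ranges that do not overlap, which argues against that explanation for this pair. For 18_3 to 35_7 the ratios were 0.891 ± 0.0509 and 0.710 ± 0.0920. A partial sharing of reads stays open, as does induction of both copies by cadmium, since the sequences were not compared. Induction of 1 copy alone was not excluded either. With its reads divided and a steady low level of the other copy, the ratio would differ between groups too.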
